A study of Mus musculus with 6 samples.

How the data were processed

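Poly(A)-based cDNA libraries were made from 2 ng of total RNA of sorted bone marrow cells with a modified SMART-seq2 protocol and Nextera XT, with ERCC spike-in RNA added, and were sequenced as paired ends of 51 cycles on a HiSeq 2500, per the labels' protocols. The protocol does not mark strand, so overlapping genes on opposite strands cannot be told apart in these counts. STAR, featureCounts and the genome build GRCm38 are named in the submitters' processing notes. Their versions, the annotation release and the settings for read pairs and multi-mapping reads are not given in the sources used here. The authors deposited 1 table of raw counts per gene, whole numbers with no normalization, for 54752 genes, with columns for the 6 libraries used here. The deposited table also gives the exons of each gene and their summed length, and the gene coordinates in the report run from the first to the last of these exon positions on GRCm38. It holds 0 spike-in entries, and columns of samples other than these 6 were not counted.

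Gene symbols were taken from the GENCODE M21 gene table for the same build by matching identifiers without their version: 54723 identifiers matched and 29 did not. Each column was assigned to its sample by the library number in the sample title, and the samples to TpMo (3 libraries) or mature Ly6Chi monocyte (3 libraries) by the title. The replicate numbers name the libraries in accession order and were not used to pair them. The labels do not say whether both populations were sorted from the same mice, so any such pairing is unknown and was not modelled. The labels give no batch. Within a population, the counts of every pair of libraries differed by far more than sampling noise (chi-square per degree of freedom of at least 26.8), so no library was treated as a repeat deposit of another.

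Genes were kept by edgeR's filterByExpr (minimum count 10, minimum total 15), leaving 13920. Library sizes were scaled with TMM factors (0.975 to 1.03). The populations were compared with edgeR 4.0.16 in R 4.3.3 (glmQLFit with robust dispersion, glmQLFTest), over all 6 libraries with no covariate, as the labels state none. P-values were adjusted with the Benjamini-Hochberg method and a threshold of 0.05 was used. Log2 differences are TpMo minus Ly6Chi, with SE taken as the log2 difference divided by the square root of the F statistic. Intervals called 95% are the estimate ± 1.96 SE, a normal approximation that is too narrow for 3 libraries against 3. Levels are TMM-scaled CPM, counts divided by the scaled library total, as mean ± SD over the libraries of a group. The common dispersion was 0.162, a coefficient of variation of 40.3% between libraries. A total of 3 counts, the limit that a count of 0 allows, corresponds, before TMM scaling, to 0.113 to 0.148 CPM in 5 libraries and to 0.459 CPM in Ly6Chi replicate 2. These limits cover counting error only, because the PCR-amplified reads carry no molecular identifiers. With 3 libraries against 3 an exact permutation test of a single gene cannot go below p = 0.1, so the moderated test across genes was used.

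Before the data were examined, 30 gene lists were fixed: 19 of pathways and monocyte states, 2 of handling and RNA quality, and 9 of other marrow cell types. Each list with at least 2 tested members (29 lists) was tested with limma 3.58.1's camera on log2 CPM values (prior count 2) against all other tested genes, two-sided, with the preset inter-gene correlation of 0.01, adjusted over the lists. With this setting 15 lists passed, 6 higher and 9 lower in TpMos. With the correlation estimated from these libraries 0 of the 29 passed camera after adjustment and 9 had an unadjusted p under 0.05. Fry, which asks only whether a list's genes move on balance in 1 direction, passed 13. The histone, inflammatory and cholesterol lists passed camera and did not pass fry (adjusted p = 0.219, 0.111 and 0.26). The dendritic cell list passed fry (adjusted p = 0.0244) and did not pass camera. Lists overlap in some members, and genes of a list are not independent replicates. The rule for named genes, fixed at the same time, took 10 population markers, the 5 genes with the largest difference in each direction among those past the threshold with at least 5 log2 CPM and no overlap between the populations (leaving out unnamed and predicted genes), the 2 members with the smallest p in each pathway list that passed camera, and the most abundant tested member of each handling and cell type list, 51 genes in all, of which 2 are not reported here. Other list members are named where few members passed, or as said beside them, after their values were seen.

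The steps were tested on simulated counts drawn from the means, dispersions and library sizes of the real libraries. For the simulated comparison of TpMo against Ly6Chi on 13357 genes with 200 changed, edgeR recovered 45% of genes changed by 1 and 87% of genes changed by 2 on the log2 scale, with 6.38% of its calls false and 0 in the wrong direction. DESeq2 recovered 65% and 95% with 24.5% of its calls false. The changed genes were drawn only from those above a minimum mean CPM. They were also a far smaller share of genes than was called in the real comparison. The recovered and false shares need not hold there, least of all for genes of low level. In a second simulation on 13333 genes camera called 10 of 10 lists of 40 genes shifted by 0.7 and 0 of 50 unshifted lists, with either correlation setting; the simulated genes were drawn independently. Alternatives fixed before the data were examined were RLE factors, no low-count filter (at least 1 count), a stricter filter (20 counts in 3 libraries), DESeq2 1.42.0, limma-voom, TMM factors estimated without the proliferation, ribosomal and mitochondrial lists, the estimated correlation, and leaving out each library. Spike-in scaling was planned and not run, because the table holds no spike-in counts. Thinning all libraries to the total of the shallowest was added after seeing the data. Sham-operated animals were not analysed here.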

Results

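Gene expression was measured by RNA sequencing in 2 bone marrow monocyte populations sorted from mice 6 days after cecal ligation and puncture, a surgical model in which gut bacteria leak into the abdomen and cause sepsis. The titles of the libraries describe the sepsis as of middle grade. The first population, TpMos, is known from earlier work as transitional pre-monocytes, an intermediate between committed monocyte progenitors and mature monocytes that is marked by the chemokine receptor CXCR4. The second population was mature Ly6Chi monocytes, the classical inflammatory monocytes of the mouse. Each population had 3 libraries. Sham-operated mice are named in the study design and were not analysed here, so every value below describes cells from septic animals. The libraries held 20228271, 26492791 and 25098298 counts for TpMos and 21161348, 6530656 and 24354629 counts for Ly6Chi monocytes, replicates 1 to 3 in each case. Ly6Chi replicate 2 was the shallowest, and 15570 genes had at least 1 count in it against 17348 to 17657 genes in the others. The labels do not say whether the 3 libraries of a group came from separate mice, so the p-values measure the spread between these libraries, part of which may be technical.

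The comparison asked how TpMos and mature Ly6Chi monocytes differ in the septic marrow. Higher in TpMos were 52 of 54 genes of S phase, 63 of 64 of G2 and mitosis and 20 of 45 of ribosome assembly. So were 11 of 19 genes (with 1 lower) of a mixed list of primary granule and progenitor genes. Higher in mature Ly6Chi monocytes were 35 of 45 genes of mature monocytes (with 1 lower), 7 of 15 of MHC class II presentation, 21 of 46 of the interferon response and 16 of 40 of the lysosome and phagocyte oxidase. Each of these lists passed camera with a preset correlation, and with an estimated correlation 0 of 29 lists passed (smallest adjusted p = 0.063; 9 lists at an unadjusted p under 0.05). Of 13920 genes tested, 3133 (22.5%) differed at an adjusted p under 0.05 in edgeR's quasi-likelihood test, with 1772 higher and 1361 lower in TpMos. The difference exceeded 1 on the log2 scale for 1159 of the higher and 876 of the lower genes. The first principal component of the log2 CPM values held 49.1% of the variance and separated the populations. Pearson correlations across genes were 0.921 to 0.948 within a population and 0.859 to 0.898 between populations. The values of the populations did not overlap for 5782 genes (41.5%), where chance gives 10% in a comparison of 3 against 3. Without Ly6Chi replicate 3 the count of lower genes was 822.

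The genes that define the populations in earlier work or by label differed as follows. Cxcr4 (chromosome 1, 128588199 to 128592293, GRCm38), the receptor that retains cells in marrow, was 4.39-fold higher in TpMos, at 38.7 ± 3.27 CPM against 8.77 ± 0.417 CPM (SD, n = 3 each, adjusted p = 0.0002). As CXCR4 is used to sort TpMos in earlier work, this value checks the labels and is not a finding. Csf1r, the receptor for the monocyte growth factor CSF1, was 1.78-fold higher in Ly6Chi monocytes (1608 ± 61.2 against 904.5 ± 132 CPM, adjusted p = 0.00315). Ccr2, the receptor that drives monocyte exit from marrow, was 1.68-fold higher in Ly6Chi monocytes (3033 ± 445 against 1807 ± 224 CPM, adjusted p = 0.00782). Cx3cr1, a fractalkine receptor, was 5.64-fold higher there (adjusted p = 0.000401), and the integrin gene Itgam was 3.48-fold higher (adjusted p = 5.19e-05). Flt3, a cytokine receptor best known from progenitors and dendritic cells, was also higher in Ly6Chi monocytes, at 26.6 ± 6.05 CPM against 4.56 ± 3.08 CPM (adjusted p = 0.00792). Ly6c2, which encodes the Ly6C antigen and has the near-identical neighbour Ly6c1, had 2111 ± 712 CPM in TpMos and 1607 ± 308 CPM in Ly6Chi monocytes and did not pass the test (adjusted p = 0.32). Without TpMo replicate 2, Ly6c2 was higher in TpMos by 0.65 on the log2 scale (adjusted p = 0.0287, and 0.0287 to 0.667 over its 13 alternatives). The stem cell factor receptor gene Kit (0.934 ± 0.811 and 1.35 ± 1.27 CPM, adjusted p = 0.79) did not pass either.

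**Figure D1:**
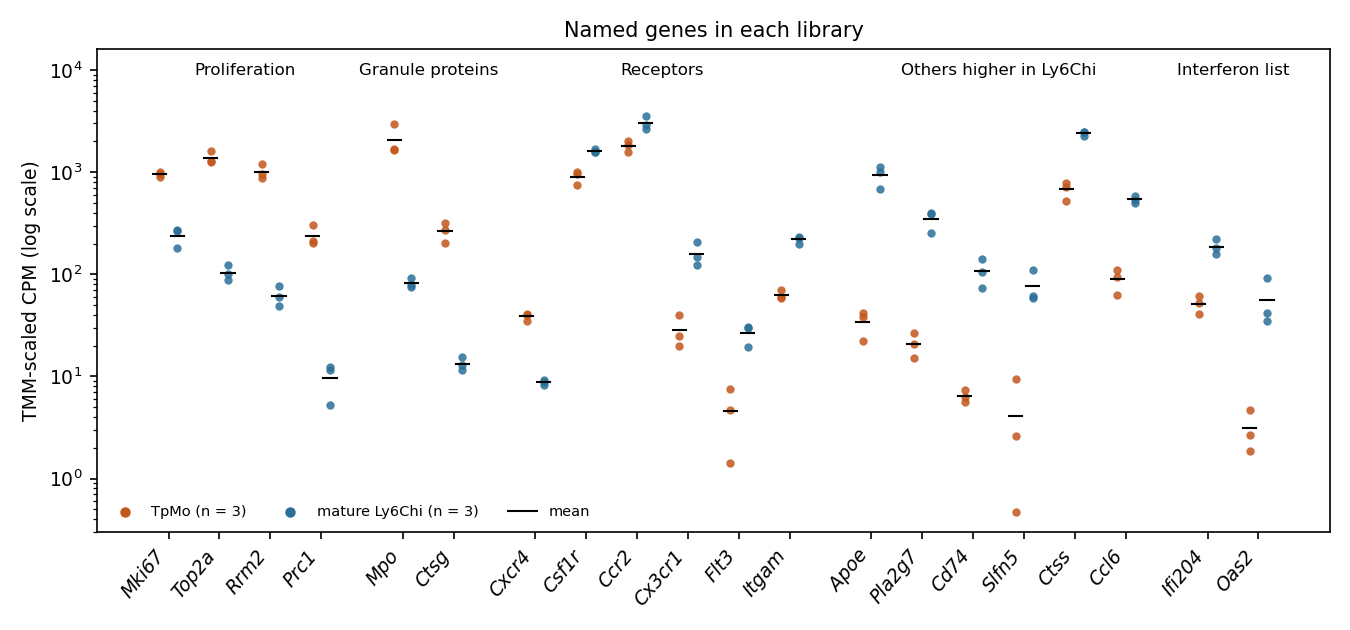
TMM-scaled CPM (log axis) of named genes in each library, with TpMos in orange and mature Ly6Chi monocytes in blue (n = 3 libraries each), and the group mean as a black line. Mpo and Top2a are higher in every TpMo library, and Apoe and Cd74 are higher in every Ly6Chi library.

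Proliferation genes formed the broadest difference. Of 54 tested S phase genes, 52 were higher in TpMos and 0 were lower, with a median fold of 7.74. Rrm2, a subunit of the enzyme that makes deoxyribonucleotides, had 1016 ± 164 CPM in TpMos and 61.8 ± 13.8 CPM in Ly6Chi monocytes (log2 difference 4.03 ± 0.21 SE, adjusted p = 1.16e-05). E2f8, a transcription factor of the S phase programme, was 11.4-fold higher (adjusted p = 1.16e-05). Of 64 tested genes of G2 and mitosis, 63 were higher and 0 were lower, with a median fold of 6.37. Top2a, the topoisomerase that untangles chromosomes, had 1386 ± 191 CPM against 104 ± 16.8 CPM (log2 difference 3.73 ± 0.18 SE), and Nusap1, a spindle protein, was 12.8-fold higher (both adjusted p = 1.16e-05). Mki67 (chromosome 7, 135689784 to 135716361), which encodes the proliferation antigen Ki-67, was 4.0-fold higher, at 956 ± 53.3 CPM against 239 ± 50.8 CPM (adjusted p = 7.4e-05). Adjusted over the list alone, 53 S phase genes were higher and 0 were lower, and for G2 and mitosis 63 were higher and 1 was lower. The 2 lists passed camera against all other genes with adjusted p = 5.55e-34 for S phase and 3.02e-36 for G2 and mitosis. With an estimated correlation the adjusted p was 0.063 for each. The selection rule considered genes of at least 5 log2 CPM. Among those, the largest differences in favour of TpMos included the mitotic spindle protein Prc1 (23.7-fold, adjusted p = 2.28e-05), the cohesin acetyltransferase Esco2 (24.4-fold, adjusted p = 3.12e-05) and the centromere protector Sgo1 (19.9-fold, adjusted p = 5.18e-05).

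Replication-dependent histone genes were a partial case. Of 42 tested, 4 were higher in TpMos, 1 was lower and 37 did not pass, and adjusted over the list alone 1 was higher and 0 were lower. The linker histone gene Hist1h1b had 23.1 ± 3.88 CPM in TpMos and 4.32 ± 3.09 CPM in Ly6Chi monocytes (adjusted p = 0.00535), and Hist1h2ap had 3.10 ± 1.5 against 0.297 ± 0.283 CPM (adjusted p = 0.0229). Most of these transcripts lack a poly(A) tail, which the library protocol needs, and the H2a copies are near-identical, so Hist1h2ap is uncertain. Camera gave adjusted p = 0.0037 with a median log2 difference of 1.00, and adjusted p = 0.635 with an estimated correlation. The other members past the threshold were Hist1h2ag and Hist1h2ab, higher in TpMos, and Hist2h2be, lower. Without TpMo replicate 2 the median was 0.43 and the list did not pass (adjusted p = 0.101, and 2.89e-07 to 0.127 over its 12 alternatives), and Hist1h2ap did not pass without TpMo replicate 2 or without Ly6Chi replicate 1 or 3. Without Ly6Chi replicate 2 the list median was 1.88, Hist1h1b was at 3.17 and Hist1h2ap at 4.46 on the log2 scale (lowest with 1 library left out, 2.18 and 3.07).

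The preset list of primary granule and progenitor granule proteins also holds genes of other proteins, Calr and Igfbp4 among them. Of its 19 tested members, 11 were higher in TpMos and 1 was lower. Mpo (chromosome 11, 87793581 to 87804413), which encodes myeloperoxidase, differed by 4.67 ± 0.26 SE on the log2 scale, at 2086 ± 738 CPM against 82.1 ± 8.46 CPM (25.4-fold, adjusted p = 1.18e-05). Ctsg, which encodes the protease cathepsin G, was 20.0-fold higher, at 264 ± 58.5 against 13.3 ± 1.94 CPM (adjusted p = 1.16e-05). The lower member was the eosinophil-associated ribonuclease gene Ear2 (log2 difference -1.15, adjusted p = 0.0299). Adjusted over the list alone, 11 were higher and 4 were lower. The list's median log2 difference was 0.69, and camera gave adjusted p = 0.00156, or adjusted p = 0.373 with an estimated correlation. The list of stem and progenitor genes held no common direction: of 20 tested, 4 were higher in TpMos, 3 were lower and 13 did not pass (5 higher and 5 lower adjusted over the list alone). Myc, Myb, Hoxa9 and Irf8 were higher in TpMos, and Zeb2, Cd93 and Flt3 were lower. Its median was -0.07 while its mean was 0.56 and camera pointed upward, without passing (adjusted p = 0.679).

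Ribosome assembly genes were also higher in TpMos, as were a few metabolic genes. Over all tested genes 1772 of 13920 were higher in TpMos. The shares called higher in the respiratory chain and cholesterol lists below did not exceed that one. Of 45 tested factors of ribosome biogenesis, 20 were higher and 0 were lower (24 and 0 adjusted over the list alone), with a median fold of 1.57. The nucleolar protein genes Nop58 (147 ± 17.3 against 30.6 ± 5.49 CPM, adjusted p = 5.18e-05) and Nop56 (234 ± 17 against 69.7 ± 3.48 CPM, adjusted p = 4.34e-05) were 4.77-fold and 3.35-fold higher. Camera gave adjusted p = 2.62e-08, and adjusted p = 0.112 with an estimated correlation. Of 85 tested ribosomal protein genes 0 passed in edgeR, over all genes or adjusted over the list alone, while 2 were higher and 1 was lower at an unadjusted p under 0.05. DESeq2 called 1 of them lower and limma-voom called 1 higher. Their median log2 difference was 0.02 (adjusted p = 0.679). Of 71 nuclear respiratory chain genes, 6 were higher and 0 were lower (4 and 0 adjusted over the list alone; camera adjusted p = 0.542). Of 21 glycolysis genes, 6 were higher and 2 were lower, the same counts as adjusted over the list alone (camera adjusted p = 0.0699). Of 24 cholesterol synthesis genes, 3 were higher and 1 was lower, the same counts as adjusted over the list alone (camera adjusted p = 0.0459, or p = 0.668 adjusted with an estimated correlation). The sterol enzyme gene Dhcr7 was 2.17-fold higher in TpMos (adjusted p = 0.0193), the acetyl-CoA acetyltransferase gene Acat2 was 2.43-fold higher (adjusted p = 0.013) and Stard4 was also higher, while Mvd was lower. The cholesterol list did not pass without TpMo replicate 1 (adjusted p = 0.0641), TpMo replicate 2 (0.115) or Ly6Chi replicate 3 (0.197), within a range of 0.00666 to 0.197 over its 12 alternatives. Dhcr7 did not pass without TpMo replicate 1 or 2 or Ly6Chi replicate 2 or 3 (adjusted p up to 0.0664), nor Acat2 without Ly6Chi replicate 2 or 3 (up to 0.0561).

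Genes of mature classical monocytes were higher in the Ly6Chi libraries for 35 of 45 tested members, with 1 (Spn, which encodes CD43) higher in TpMos and 9 not past the threshold (36 and 1 adjusted over the list alone). Ccl6, a chemokine gene of myeloid cells, had 541 ± 37.9 CPM in Ly6Chi monocytes and 89.4 ± 23.8 CPM in TpMos (6.05-fold, adjusted p = 4.19e-05). Itgam was the other leading member, at 220 ± 18.2 against 63.2 ± 6.29 CPM. The list median was -1.26 on the log2 scale, and camera gave adjusted p = 1.4e-12, or adjusted p = 0.063 with an estimated correlation. Of 28 receptors and integrins of chemotaxis and marrow retention, 14 were higher in Ly6Chi monocytes and 2 (Cxcr4 and S1pr4) in TpMos (17 and 3 adjusted over the list alone). C5ar1, the receptor for complement fragment C5a, was 5.73-fold higher in Ly6Chi monocytes (113 ± 20.7 against 19.7 ± 3.56 CPM, adjusted p = 5.34e-05). This list passed camera with adjusted p = 3.82e-05, and had adjusted p = 0.115 with an estimated correlation. Some neutrophil genes differed in the same direction: 5 of 17 tested (Mmp8, Csf3r, Cd177, Padi4 and Itgb2l, the same count adjusted over the list alone) were higher in Ly6Chi monocytes, led in level by the collagenase gene Mmp8 (1434 ± 222 against 496 ± 110 CPM, adjusted p = 0.000497), and that list did not pass camera (adjusted p = 0.0842) except without Ly6Chi replicate 3 (0.0205, with 0.0205 to 0.207 over its 12 alternatives).

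Genes of microbial sensing and degradation were higher in Ly6Chi monocytes. Of 36 tested pattern recognition genes, 22 were higher there and 1 (Lbp) was higher in TpMos (27 and 1 adjusted over the list alone). The lectin receptor gene Clec4d had 18.5 ± 5.76 CPM in Ly6Chi monocytes and 1.72 ± 0.331 CPM in TpMos (10.7-fold, adjusted p = 0.000352). Tlr7, a sensor of single-stranded RNA, had 89.5 ± 14.0 against 14.3 ± 6.54 CPM (6.25-fold, adjusted p = 0.000666). The camera test of the list gave adjusted p = 8.77e-08, and adjusted p = 0.109 with an estimated correlation. Of 40 genes of the lysosome and the phagocyte oxidase, 16 were higher in Ly6Chi monocytes and 0 in TpMos (20 and 1 adjusted over the list alone). The protease gene Lgmn was 3.55-fold higher in Ly6Chi monocytes (279 ± 36.5 against 78.7 ± 10.4 CPM, adjusted p = 8.62e-05). The lysosomal list had a camera adjusted p = 0.00015, and adjusted p = 0.112 with an estimated correlation.

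Genes of MHC class II presentation were higher in Ly6Chi monocytes for 7 of 15 tested members and higher in TpMos for 0, with the same counts adjusted over the list alone. The list also holds genes of other proteins, Ctss and Cd86 among those that passed. H2-DMa, H2-DMb1, H2-DMb2, H2-Oa and H2-Ob did not pass (adjusted p = 0.112 to 0.776, edgeR). Cd74 (chromosome 18, 60803848 to 60812646), the invariant chain of class II molecules, had 107 ± 33.6 CPM in Ly6Chi monocytes and 6.43 ± 0.896 CPM in TpMos (16.6-fold, adjusted p = 2.13e-05). Ctss, a protease that trims the invariant chain, had 2401 ± 135 against 678 ± 134 CPM (3.54-fold, adjusted p = 8.9e-05). In camera the class II list had adjusted p = 8.19e-05, and adjusted p = 0.16 with an estimated correlation. MHC class I genes passed for 3 of 18 members (H2-T23, H2-D1 and Psmb10), each higher in Ly6Chi monocytes (2 adjusted over the list alone), and the list did not pass camera (adjusted p = 0.104). Macrophage genes were higher in Ly6Chi monocytes for 7 of 16 members and in TpMos for 0 (8 and 0 adjusted over the list alone). Among them Apoe (chromosome 7, 19696109 to 19699188), which encodes a lipid carrier, had 935 ± 230 CPM against 34.2 ± 10.4 CPM. Its log2 difference of -4.77 ± 0.30 SE was the largest in favour of Ly6Chi monocytes among the genes of at least 5 log2 CPM that the selection rule considered. The macrophage list had a camera adjusted p = 0.00281, and adjusted p = 0.112 with an estimated correlation. Its median was -1.09, and -1.70 without TpMo replicate 1 (-1.70 to -1.06 with 1 library left out). Pla2g7, which encodes a secreted phospholipase that degrades platelet-activating factor, was 16.7-fold higher in Ly6Chi monocytes (adjusted p = 1.9e-05). Of 8 tested dendritic cell genes, 2 (Tcf4 and Flt3) were higher in Ly6Chi monocytes, again the same count adjusted over the list alone. That list did not pass camera (adjusted p = 0.0733) and passed fry (adjusted p = 0.0244). Its most abundant member was the transcription factor gene Tcf4 (99.7 ± 12.1 against 40.7 ± 5.02 CPM, adjusted p = 0.000939).

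Interferon-stimulated genes were higher in Ly6Chi monocytes for 21 of 46 tested members and in TpMos for 0 (25 and 0 adjusted over the list alone). Oas2, an antiviral oligoadenylate synthetase gene, had 56.2 ± 31.4 against 3.09 ± 1.48 CPM (18.4-fold, adjusted p = 0.000339), and Ifi204, a DNA sensor gene of a family of close paralogs, was 3.62-fold higher (adjusted p = 0.000227). The list median was -1.22, and -1.64 to -0.78 with 1 library left out. Camera gave adjusted p = 2.62e-08, or adjusted p = 0.383 with an estimated correlation. Slfn5, a Schlafen family gene, had 76.4 ± 29.0 CPM against 4.14 ± 4.64 CPM (adjusted p = 0.00511, 0.109 without the low-count filter, and 0.000495 to 0.109 over its 13 alternatives). Its log2 difference was -4.23, and -5.625 without TpMo replicate 1 (-5.625 to -3.69 with 1 library left out). Of 26 cytokine, chemokine and inflammatory mediator genes, 9 were higher in Ly6Chi monocytes and 0 in TpMos (11 and 0 adjusted over the list alone). Il18, an inflammasome-released cytokine, had 17.8 ± 2.50 against 1.65 ± 1.53 CPM (adjusted p = 0.00369), a log2 difference of -3.42, and of -4.52 without TpMo replicate 3 (-4.52 to -3.04 with 1 library left out). Saa3, an acute phase protein gene, had 150 ± 123 against 8.05 ± 5.20 CPM (adjusted p = 0.00732) and did not pass without TpMo replicate 3 (adjusted p = 0.0557) or without the low-count filter (0.103), with 9.7e-05 to 0.103 over its 13 alternatives. Its log2 difference was -4.20, and -4.82 without TpMo replicate 2 or -3.47 without Ly6Chi replicate 2. The inflammatory list had a camera adjusted p = 0.000512, and adjusted p = 0.446 with an estimated correlation. It did not pass fry (adjusted p = 0.111). Its median was -1.19, and with 1 library left out it ranged from -1.95 (without TpMo replicate 2) to -0.71 (without Ly6Chi replicate 2). Of 16 glucocorticoid-induced genes, 4 were higher in Ly6Chi monocytes and 0 in TpMos (11 and 0 adjusted over the list alone). They were led by Txnip, a regulator of redox state and glucose uptake (205 ± 18.1 against 76.5 ± 21.4 CPM, adjusted p = 0.00114), and the kinase gene Map3k6 (59.0 ± 5.29 against 22.6 ± 6.05 CPM, adjusted p = 0.00263), and Tsc22d3 and Fkbp5 also passed. The camera adjusted p was 0.00097, and adjusted p = 0.109 with an estimated correlation.

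**Figure D2:**
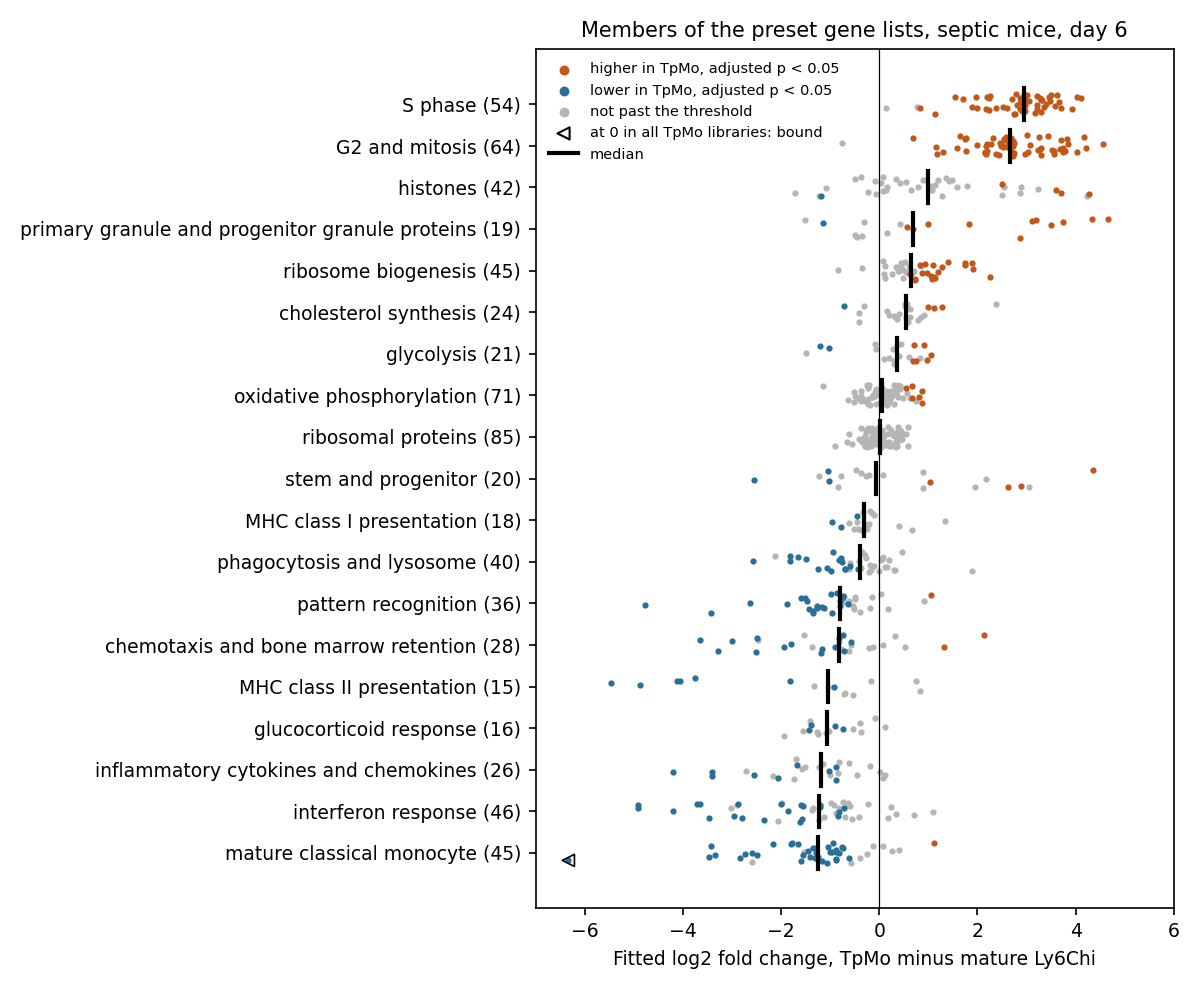
Log2 difference (TpMo minus mature Ly6Chi, horizontal axis) of each tested member of the 19 preset biological gene lists, with the number tested in brackets, the median as a black bar and members past an adjusted p of 0.05 in orange (higher in TpMos) or blue (lower in TpMos). The triangle marks a gene with no counts in any TpMo library, drawn at its bound. S phase and G2 and mitosis lie to the right, with medians of 2.95 and 2.67, and mature classical monocyte genes lie to the left, with a median of -1.26.

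Markers of other marrow cells and of handling were measured as background. No gene of the 22 in the T and NK cell list had enough counts to be tested, and the highest value of any of them in any library was 0.642 CPM before TMM scaling, for Cd247. Of 4 tested B lineage genes 0 passed in edgeR, DESeq2 or limma-voom, with 0 at an unadjusted p under 0.05 in each, and Ighm, the immunoglobulin heavy chain constant region gene, was at 545 ± 87.0 CPM in TpMos and 454 ± 69.5 CPM in Ly6Chi monocytes. Of 13 erythroid genes 1 passed, over all genes and adjusted over the list alone, the transferrin receptor gene Tfrc (68.0 ± 25.8 CPM in TpMos and 6.51 ± 2.30 CPM in Ly6Chi monocytes, adjusted p = 0.000187), which proliferating cells of other lineages also use. Of 5 stromal and endothelial genes 1 passed, again by both adjustments, the adhesion gene Pecam1, which leukocytes also express (39.9 ± 5.34 and 10.5 ± 1.21 CPM, adjusted p = 0.000462). Hdc, the most abundant of the mast cell, basophil and eosinophil genes, was at 3.34 ± 1.70 and 3.24 ± 1.71 CPM, and Itgb3 led the megakaryocyte list at 13.8 ± 11.4 and 11.1 ± 12.9 CPM, with 0 genes past the threshold in either list in edgeR, DESeq2 or limma-voom, and at an unadjusted p under 0.05 with 1 of 6 and 0 of 2 genes in each. Early response and heat shock genes split, with 4 higher and 4 lower in TpMos of 23 tested (5 and 4 adjusted over the list alone; camera adjusted p = 0.543), and the chaperone gene Hspa8 was at 5778 ± 1346 and 3908 ± 742 CPM without passing (adjusted p = 0.0739). Of 13 mitochondrially encoded genes 1 was higher in Ly6Chi monocytes (0 adjusted over the list alone), mt-Co1 (7574 ± 1917 against 4959 ± 726 CPM, adjusted p = 0.0481), and it did not pass when any library was left out (adjusted p up to 0.17). The lists without a p above were not past camera, with adjusted p = 0.513 for B lineage, 0.0878 for erythroid, 0.229 for mast cell, basophil and eosinophil, 0.911 for megakaryocyte, 0.911 for stromal and 0.119 for mitochondrial genes. Where a count of 0 is given for a direction in a list, edgeR found 1 member in that direction at an unadjusted p under 0.05 for G2 and mitosis, interferon, macrophage and erythroid genes each, 2 for lysosomal genes, 3 for MHC class I and for respiratory chain genes each, and 0 for the other lists. DESeq2 called 1 such member among interferon, lysosomal, MHC class I and respiratory chain genes each, limma-voom called 1 among interferon and respiratory chain genes each, and both called 0 in the other lists. Transcripts of the mitochondrial chromosome took 0.984% to 1.76% of counts in TpMos and 1.67% to 2.57% in Ly6Chi monocytes.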

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

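The thinning to the shallowest library was chosen after seeing the data. The total, higher and lower counts and those beyond 1 on the log2 scale stayed within 1.5 times of the reported ones under every alternative run, except that the genes lower in TpMos fell to 822 without Ly6Chi replicate 3 (822 to 1199 with 1 library left out). The total ranged from 2127 to 2757 with 1 library left out and from 3124 to 3929, in DESeq2, under the other alternatives. Of the 3133 genes called, 64.9% to 79.4% were called again with 1 library fewer and 93.9% to 99.4% under the other alternatives, and 0 of those tested again changed sign. Of the 15 gene lists past camera, 0 passed with an estimated correlation (9 of 29 lists at an unadjusted p under 0.05). Reversed directions, by camera for lists, belonged to results that did not pass the test in either fit. For ribosomal proteins the median was -0.05 without Ly6Chi replicate 1 and -0.056 without replicate 3 (-0.056 to 0.19 with 1 library left out), with a call without Ly6Chi replicate 2 (adjusted p = 0.0231, and 0.0231 to 0.822 over the alternatives). For early response genes it was -0.27 without TpMo replicate 3 (-1.45 to -0.15), and for B lineage genes -0.038 without a low-count filter and 0.034 without Ly6Chi replicate 3 (-0.018 to 0.35). The megakaryocyte median was -0.11 in limma-voom, and the stromal one -0.35 in limma-voom and -0.52 after thinning. Hdc was -0.11 after thinning and -0.42 to 0.55 with 1 library left out, below 0 without TpMo replicate 2 or Ly6Chi replicate 2 or 3. Itgb3 was -0.61 to 1.92, below 0 without TpMo replicate 1 or Ly6Chi replicate 2 or 3. Kit was 0.0058 in limma-voom and -1.47 to 0.54, above 0 without Ly6Chi replicate 2. Glycolysis, dendritic cell, mast cell, erythroid and mitochondrial lists and Hspa8 passed under some alternatives, with lowest adjusted p of 0.0199, 0.00977, 0.0297, 0.0487, 0.0474 and 0.0222. The histone list did not pass after thinning, nor the cholesterol list under the stricter filter, nor mt-Co1 with TMM factors estimated without the proliferation, ribosomal and mitochondrial lists. The cause was not tested. Of the genes with no counts in 1 population only Ace is in a tested list, and with it at its bound of -6.34 the mature monocyte median stays -1.26, as Ace lies below it either way. Spike-in scaling was not run, as the table holds 0 spike-in entries. No paired analysis was possible because the labels number no replicates and name no animal. Ly6Chi replicate 2 held 6530656 counts, which limits what can be seen of genes under 0.459 CPM (before TMM scaling) in it.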

Other observations

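Among the tests in this part, the share of TpMo transcripts in the Ly6Chi libraries and the dendritic cell and B cell tests of Cd74 were chosen after the result was seen. The genes of the first 2 paragraphs were picked after their values were seen, from the preset lists and from the genes with large differences, and Prc1, Ccnb2 and Pttg1 further down were also picked after theirs were seen. Some mature monocyte genes are also markers of patrolling Ly6Clo monocytes, and those named here were not tested as a group. Nr4a1, a transcription factor that patrolling monocytes need and that is also an early response gene of the handling list, had 76.8 ± 22 CPM against 11.4 ± 7.44 CPM in TpMos (adjusted p = 0.00236, edgeR, n = 3 each). Treml4 was 10.1-fold higher (adjusted p = 0.00243), the Fc receptor gene Fcgr4 10.8-fold (0.000424), Adgre4 11.2-fold (0.000291) and Klf2 7.11-fold (0.00303). Ace had no counts in any TpMo library and 10.3 CPM in Ly6Chi monocytes, at least 80.8-fold lower in TpMos with 3 counts per TpMo library as the floor (adjusted p = 0.000142). Spn, which encodes CD43 and is also a patrolling monocyte marker, went the other way, at 80.3 ± 7.86 CPM in TpMos and 37.1 ± 7.42 CPM in Ly6Chi monocytes (adjusted p = 0.00368). S1pr5 (adjusted p = 0.21), Itgal (0.052), Itgax (0.289) and Cd36 (0.822) did not pass.

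Sirpb1a, Sirpb1b and Sirpb1c, activating relatives of the SIRPα receptor, were 12.3-fold, 6.34-fold and 10.9-fold higher in Ly6Chi monocytes (adjusted p = 1.49e-05, 2.13e-05 and 1.16e-05 in edgeR), and the CD300 family genes Cd300ld and Cd300c2 were 11.9-fold and 9.25-fold higher (0.000255 and 0.000126). Members of each family share sequence, so how reads were divided between them is uncertain. Of the 7 heat shock genes tested in the handling list, Hsp90aa1 (5.23-fold, adjusted p = 1.95e-05), Hsph1 (3.46-fold, 0.00102), Dnajb1 (2.39-fold, 0.0219) and Hspe1 (1.84-fold, 0.0398) were higher in TpMos and 3 did not pass (Hspa8, Hspa1a and Hspa1b, adjusted p = 0.0739 to 0.733), while of its 16 other genes Nr4a1 (6.70-fold, 0.00236), Atf3 (7.21-fold, 0.00819), Ier5 (7.77-fold, 0.00301) and Ier2 (2.24-fold, 0.0124) were higher in Ly6Chi monocytes and 12, Fos, Jun and Egr1 among them, did not pass (0.0972 to 0.9).

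The count of 3133 genes was the highest among the 10 ways to split the 6 libraries 3 against 3, where 1 split, the real one, reached it and the highest other gave 0 in edgeR. With 10 splits a share under 0.05 cannot be reached. Every other split mixes the 2 populations on both sides, which widens the spread within a side. Its count of 0 is therefore no estimate of false calls.

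Genes of G2 and mitosis kept very different shares of their TpMo level in mature Ly6Chi libraries: Prc1 4.22% (95% interval 2.73 to 6.53), Top2a 7.52% (5.87 to 9.63), Mki67 25% (19.6 to 31.9), Ccnb2 62.5% (52.0 to 75.2) and Pttg1, higher there without passing the threshold (adjusted p = 0.123), 171% (110 to 264). TpMos carried into the Ly6Chi gate in 1 fixed proportion would hold all TpMo transcripts at or above 1 ratio, and could raise a gene no further than Mpo, at 3.93% (upper bound 5.62), or Ctsg, at 4.99% (upper bound 6.77). The median over the 64 tested genes of G2 and mitosis was 15.7%, and for 50 of them, Prc1 and Top2a not among them, the whole interval lay above both bounds, which argues against such carry-over as the whole source. A hypothesis that stays open is that some Ly6Chi monocytes of septic marrow are in or just past the cell cycle. Carry-over of a late TpMo subset that is low in Mpo stays open too. The bulk values here do not tell these 2 apart. Sorted cells of sham mice would be needed to relate either to sepsis, and would not separate them.

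Apoe and Cd74 were higher in Ly6Chi libraries together with macrophage list genes, so other cells in the gate were considered. Of the 16 tested macrophage list genes, 7 were higher there, Apoe among them. The other 9 did not pass, and 4 of these had estimates higher in TpMos. Macrophages cannot be told apart from expression by the monocytes: C1qb, a complement gene of macrophages, was also higher in Ly6Chi libraries (8.98 ± 6.15 against 0.473 ± 0.379 CPM, adjusted p = 0.00903, edgeR), and C1qa was not past the threshold (0.084). The sum of C1qa, C1qb and C1qc was at most 1.69% of Apoe there, under a bound of 10% set before these genes were looked at, but that bound was wrong as an exclusion because C1qb rose with Apoe, as macrophages in the gate would make it. The values argue against B cells as the main source of Cd74. Cd79a and Igkc together were at most 1.46% of Cd74 in any Ly6Chi library. No B cells were measured here to give the ratio they would have. The log2 differences of Cd79b, Igkc and Blnk had lower 95% bounds of -0.38, -1.13 and -1.25, all above the upper bound of -3.51 for Cd74. That comparison of folds adds little. A gene with its own TpMo level, such as Cd79b at 7.06 to 15.9 CPM, would change by a smaller fold if B cells were added. Ighm, at 545 CPM in TpMos, would hide a small share and was left out. Dendritic cells cannot be told apart from the monocytes as a source of Cd74, as the 8 tested dendritic cell genes had a median of -0.63 with 2 past the threshold, and a difference between the 2 monocyte stages, not tested otherwise, stays open too.

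Ighm was among the abundant transcripts of both populations, at 386 to 646 CPM in the 6 libraries. The B lineage genes Cd79a, Cd79b and Igkc had a sum of at most 3.32% of Ighm in any library, under a bound of 10% set before these genes were looked at, with Cd79a at 0 to 0.985 CPM, Igkc at 0.335 to 1.24 CPM and Cd79b at 6.48 to 15.9 CPM. This argues against B lineage cells in both sorts as the main source of Ighm, though not against a small share of them. No biological explanation was tested.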
